A study of Homo sapiens with 32 samples.

How the data were processed

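The data were 32 sequencing libraries from human RPE-1 cells: 16 of total RNA after removal of ribosomal RNA (RNA-seq) and 16 of ribosome-protected fragments (Ribo-seq footprints). Per the labels, cells had been without serum for 18 h and were collected at 0, 5, 10 or 15 h after serum was added, with 4 biological replicates at each time for each assay. The deposited table holds counts, as whole numbers per gene and library with no normalisation. Alignment with STAR 2.5.4a to GRCh38 and counting with featureCounts 1.5.1 are as per the submitters' processing notes; the annotation release, strand setting, adapter and molecular identifier handling and counting parameters were not given in the sources used here. The table has 19023 genes by Ensembl identifier, of which 18905 were matched to a symbol through the annotation and 6 symbols were shared by several identifiers; 2193 genes had no count in any library. The deposited length of each gene was a multiple of 3 in 96.46% of genes, so it is read as coding length. Each of the 32 columns was matched to a sample by its label, and 0 columns were left unmatched. No library was left out of the main results. Counts of genes with paralogs or pseudogenes, such as ribosomal protein and histone genes, depend on how shared reads were assigned, which was not given in the sources used here.

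The total count per library ran from 595851 to 1107470 in RNA-seq and from 2851423 to 9901322 in footprints. Libraries were scaled within each assay with TMM factors, and CPM values, in edgeR's usual unit, use those scaled library sizes. Genes passing edgeR filterByExpr by time group were tested, 8775 in RNA and 10959 in footprints. Each assay had its own negative binomial quasi-likelihood fit (edgeR QL, robust) over its 16 libraries with time as the only factor. The contrasts were 5 h, 10 h and 15 h against 0 h, 10 h against 5 h and 15 h against 10 h. A change of translational efficiency (TE) was the footprint log2 change minus the RNA log2 change, tested as the assay-by-time interaction in 1 edgeR QL fit over all 32 libraries and the 8736 genes that passed the filter in both assays. With no spike-in, each of these is a change relative to the other genes, not an absolute amount. A gene was called when its 2-sided p, adjusted by Benjamini-Hochberg over all genes tested in the contrast, was under 0.05. Errors beside log2 changes are standard errors from the fit, errors beside CPM and shares are SD, and n is 4 libraries per group throughout. The common biological coefficient of variation was 0.185 in RNA, 0.0547 in footprints and 0.102 in the joint fit. Intervals and floors would cover counting error only, since the counts are of reads.

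The 26 gene lists were: immediate-early and ERK-feedback genes, SRF and YAP cytoskeletal targets, quiescence and FOXO targets, G1/S E2F targets, G2/M genes, replication-dependent histones, cytosolic ribosomal proteins, other 5TOP translation genes, 5TOP non-coding host RNAs, ribosome biogenesis, cholesterol synthesis and uptake, fatty acid synthesis, ATF4 and amino acid response, cytosolic aminoacyl-tRNA synthetases, ER chaperones and unfolded protein response, extracellular matrix and TGF-beta targets, NF-kB and cytokine genes, p53 targets, glycolysis and hypoxia genes, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, proteasome subunits, autophagy and lysosome, epithelial and mesenchymal markers, retinal pigment epithelium differentiation markers, and blood cell markers. Lists with at least 5 tested members were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a contrast (23 in RNA, 24 in footprints, 23 in TE). Camera compares a list with the other genes. Members were counted as risen or fallen by the all-gene calls, and again with p adjusted over the list alone. Alternatives were camera with the correlation estimated per list and fry, which asks whether the members move, on balance, in 1 direction and does not compare them with other genes.

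The genes named were: in each contrast the 10 called genes with the largest rise and the 10 with the largest fall, with a mean CPM of at least 10 in a group compared and no overlap between the libraries of the groups (for TE, a mean CPM of at least 10 in both assays); a fixed set of serum, cell-cycle and housekeeping genes whatever their values; and up to 4 members of each list. Genes with 3 or fewer counts over a whole group are given no fold, and 2 of the genes that the rule names are not reported here. Genes of these lists that were not tested, among them CDKN1B, NCL, PLK1, RPL3 and PGK1, were not analysed here.

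The procedure was tested on simulated data made from these libraries with known changes of 1.5, 2 and 4-fold. Few genes were changed (67, 65 and 64 in the RNA setting), at 5 h only and in a single draw. Far more genes were called in most contrasts of the data, so the shares below may not hold there. In the RNA setting with 8595 genes, edgeR QL recovered 16.4%, 49.2% and 95.3% of changed genes, and 7.97% of its calls were false. In the footprint setting with 10694 genes it recovered 78.8%, 82.8% and 98.5%, with 3.41% false. In the TE setting with 8568 genes it recovered 14.9%, 69.7% and 90.9%, with 7.94% false, against 25% false for DESeq2. There limma voom with 1 variance weight per assay recovered 4.48%, 62.1% and 87.9%, with 1.92% false. For lists, the changed list was called by all of the tests, and of 25 unchanged lists camera called 0 with either correlation and fry called 1. As a check for libraries entered more than 1 time, the counts of all 48 pairs of libraries within a group were compared: chi-square per gene ran from 1.41 to 11.2, above the value for repeats of 1 library.

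The gene lists, the rule for naming genes, the tests and a set of alternatives were written before the data were examined. Those alternatives were median-ratio (RLE) factors, TMM over all 32 libraries together for TE, no filter and another filter on low counts, the 20 most abundant genes left out, only the groups compared, the replicate number as a block, a threshold of 2-fold, the DESeq2 Wald test, and leaving out each library in turn. That other filter, planned as stricter, kept 9618 genes in footprints. In RNA it kept 10133 and in TE 9302, more than the main filter. Added after seeing the data were: leaving out the RNA libraries numbered 2, leaving out the footprint libraries numbered 1 at 0 h and 15 h, and limma voom with 1 variance weight per assay for TE. Each count of called genes was also set against counts from other splits of the same libraries. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.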

Results

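Human RPE-1 cells, an immortalised line from retinal pigment epithelium that leaves the cell cycle without serum, were collected after 18 h of starvation (0 h) and at 5 h, 10 h and 15 h of serum. RNA-seq measured mRNA levels and Ribo-seq measured ribosome-protected footprints, in 4 biological replicates per time and assay. Footprints of a gene reflect both its mRNA level and the ribosomes on each mRNA. Depth per sample, as mean total count with SD over n = 4 libraries, was 745415 ± 112329 at 0 h, 853170 ± 184098 at 5 h, 949729 ± 207995 at 10 h and 1004620 ± 117162 at 15 h in RNA-seq. In footprints it was 4302370 ± 1103300, 7453830 ± 717724, 8209190 ± 1389750 and 8258040 ± 2422490 in the same order. Changes below are log2 ratios with standard errors from edgeR QL fits, n = 4 per group, and calls used a Benjamini-Hochberg adjusted 2-sided p over all genes tested. They are relative to the other genes of the assay. No library came from cells kept without serum to 5 h, 10 h or 15 h, so serum and elapsed time cannot be told apart. Values beside lists are medians over the members tested.

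**Figure D1:**
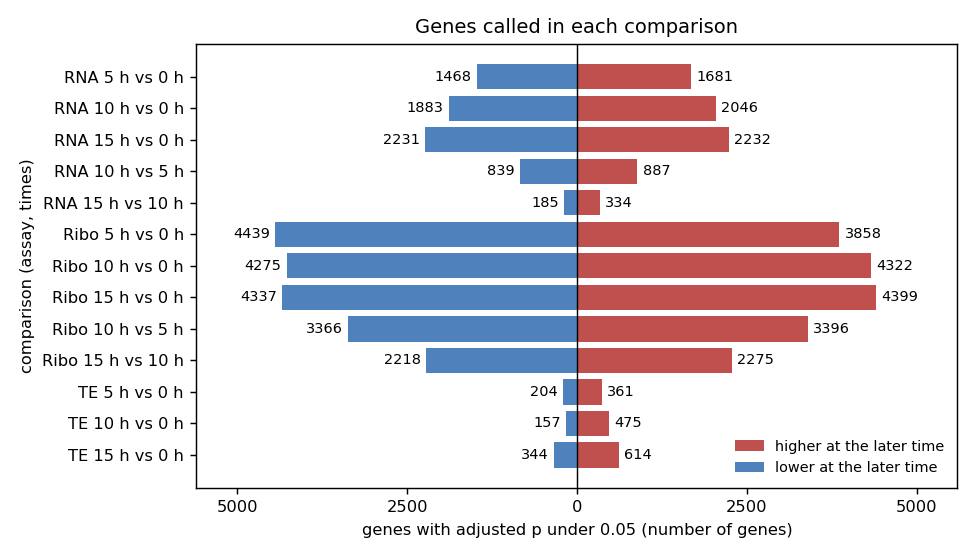
Genes called higher and lower in each contrast of RNA, footprints and translational efficiency. Footprint libraries were deeper and less variable than RNA libraries, so the counts are not on 1 scale.

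The first question was how mRNA levels had changed after 5 h of serum. CXCL8 (ENSG00000169429), which codes for the cytokine interleukin-8, rose 716-fold from 1.72 ± 1.85 to 1248 ± 84.5 CPM (9.48 ± 0.31), from 5 counts over the 0 h libraries. SERPINB2 (ENSG00000197632) rose 474-fold (8.89 ± 0.25), and F3, the tissue factor that starts clotting, rose 48.2-fold from 31.8 ± 11.8 to 1536 ± 50.7 CPM (5.59 ± 0.19). The thioredoxin-binding TXNIP fell 34.5-fold from 631 ± 57.3 to 18.7 ± 6.06 CPM (-5.11 ± 0.19), and the mitotic kinesin KIF20A fell 24.4-fold (-4.61 ± 0.21). Other large rises were PTGS2 (6.63 ± 0.38), BMP2 (5.75 ± 0.33), G0S2 (4.86 ± 0.28), IL6 (4.82 ± 0.43) and ADAMTS1 (4.71 ± 0.23). Other large falls were PIK3IP1 (-4.16 ± 0.36), PPP1R3C (-4.14 ± 0.26), IFIT1 (-3.98 ± 0.40), LRATD2 (-3.84 ± 0.22), BMP4 (-3.79 ± 0.34) and SLC2A12 (-3.74 ± 0.37). Of 8775 genes, 3149 were called, 1681 higher and 1468 lower. RLE factors gave 1564 and 1628, DESeq2 1503 and 1542, and leaving out the RNA libraries numbered 2 gave 1377 and 1624. Another filter on low counts, which kept 10133 genes, gave 1606 and 1738. Which direction held more genes thus depended on the processing.

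Several lists rose at 5 h. Of 13 NF-kB and cytokine genes, 11 rose and 0 fell (11 and 0 with p adjusted over the list alone), with a median of 2.88. Of 14 immediate-early and ERK-feedback genes, 9 rose and 1 fell (9 and 1 over the list alone, median 1.54), among them HBEGF (4.31 ± 0.29) and MYC, a transcription factor of cell growth, at 2.72 ± 0.21. Of 17 SRF and YAP cytoskeletal targets, 12 rose (13 over the list alone, median 1.17), with ANKRD1 at 3.09 ± 0.19 and CCN1 at 2.25 ± 0.33. Ribosome biogenesis rose in 23 of 27 (23 over the list alone, median 1.48), as in NIP7 (2.99 ± 0.27) and DDX21 (2.94 ± 0.15). ER chaperones rose in 18 of 19 (19 over the list alone, median 1.75), as in SDF2L1 (3.72 ± 0.28) and HSPA5 (3.11 ± 0.48). Cytosolic aminoacyl-tRNA synthetases rose in 13 of 20 and fell in 1 (14 and 1 over the list alone, median 0.72), as in GARS1 (1.47 ± 0.14) and TARS1 (1.43 ± 0.15). The fixed gene CCND1, cyclin D1, which drives entry into G1, rose 5.49-fold from 165 ± 43.6 to 903 ± 64.1 CPM.

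Quiescence and FOXO targets fell in 14 of 17 and rose in 1 (14 and 1 over the list alone, median -1.54). G2/M genes fell in 22 of 24 (22 over the list alone, median -2.25), with CDC20 at -3.71 ± 0.36 and BIRC5 at -3.52 ± 0.20. Replication-dependent histones fell in 16 of 19 (16 over the list alone, median -0.87). For both lists 0 h was thus not the lowest level, and their changes against 0 h start from there. Whether some cells were still in the cell cycle at 0 h was not tested. G1/S E2F targets were divided, 5 up and 11 down of 31 (6 and 11 over the list alone, median -0.11). CCNE2 rose (3.45 ± 0.73, from 6 counts over the 0 h libraries), while RRM2 (-2.27 ± 0.53) and TK1 (-2.05 ± 0.24) fell. Cholesterol synthesis and uptake, which sterols in serum are known to repress, fell in 13 of 23 (14 over the list alone, median -1.02), with MVK at -2.37 ± 0.24 and IDI1 at -1.73 ± 0.23. Fatty acid synthesis fell in 6 of 11 (6 over the list alone, median -0.80), with SREBF1 at -2.24 ± 0.38. Of 15 p53 targets, 2 rose and 6 fell (2 and 8 over the list alone, median -0.56), with PLK2 at -2.46 ± 0.14 and AEN at 2.20 ± 0.23. Extracellular matrix and TGF-beta targets rose in 7 of 15 and fell in 1 (7 and 1 over the list alone, median 0.15), as in LOX (1.95 ± 0.26).

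These lists were called by camera in the stated direction except the G1/S E2F targets (adjusted p = 0.309, Benjamini-Hochberg over 23 lists). With an estimated correlation the adjusted p was 0.0935 for immediate-early genes, 0.1 for histones, 0.127 for fatty acid synthesis, 0.502 for extracellular matrix genes and 0.0781 for p53 targets, so those list calls ended. The remaining lists were not called at 5 h. Cytosolic ribosomal proteins had 0 of 62 called (0 over the list alone, median -0.05), and other 5TOP translation genes 1 up and 3 down of 19 (1 and 2 over the list alone). ATF4 and amino acid response genes had 9 up and 4 down of 20 (9 and 5 over the list alone), with MTHFD2 at 3.33 ± 0.19 and DDIT4 at -3.64 ± 0.29. Glycolysis and hypoxia genes had 4 up and 4 down of 15 (4 and 5 over the list alone), with ADM at -2.70 ± 0.35 and NDRG1 at 1.79 ± 0.32. The nuclear-encoded respiratory chain had 2 up and 5 down of 45 (1 and 4 over the list alone), mitochondrially encoded mRNAs 5 down of 12 (5 over the list alone) and proteasome subunits 8 up and 3 down of 29 (8 and 3 over the list alone). Autophagy and lysosome genes had 1 up and 5 down of 17 (1 and 5 over the list alone), and epithelial and mesenchymal markers 1 up and 2 down of 7 (3 and 2 over the list alone). All 3 retinal pigment epithelium differentiation markers tested fell, MERTK (-3.08 ± 0.39), OTX2 (-2.84 ± 0.55) and MITF (-1.01 ± 0.34). The 1 blood cell marker tested, CD68, was not called (-0.56 ± 0.31). The 5TOP non-coding host RNAs were not analysed here.

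The second question was what 10 h of serum added. Genes of DNA replication rose far above their starved level. CDC6, which loads the replicative helicase, rose 46.6-fold from 7.80 ± 1.61 to 365 ± 51.6 CPM (5.54 ± 0.26), and PCNA, the sliding clamp of DNA polymerase, rose 8.26-fold from 144 ± 21.9 to 1185 ± 253 CPM (3.05 ± 0.20). CCNE2, the cyclin E2 of the G1/S transition, rose 63.2-fold (5.98 ± 0.57, from 6 counts over the 0 h libraries). The stress-induced mTORC1 inhibitor DDIT4 fell 58.4-fold from 324 ± 46.1 to 6.07 ± 4.79 CPM (-5.87 ± 0.36). Against 0 h, 3929 genes were called, 2046 higher and 1883 lower. Among the largest rises were SERPINB2 (6.25 ± 0.26), FAM111B (5.68 ± 0.51), ADAMTS1 (5.36 ± 0.23) and MCM10 (4.96 ± 0.25). Among the largest falls were TCP11L2 (-5.91 ± 0.37), PIK3IP1 (-5.80 ± 0.42), SLC2A12 (-5.26 ± 0.43) and PPL (-4.68 ± 0.38).

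At 10 h, 30 of 31 G1/S E2F targets rose (30 over the list alone, median 2.94), and replication-dependent histones rose in 17 of 19 (17 over the list alone, median 1.30), with H1-5 at 3.44 ± 0.18. G2/M genes were divided against 0 h, 12 up and 5 down (13 and 5 over the list alone), with CDK1 at 2.96 ± 0.39 and KIF20A at -2.62 ± 0.17. Ribosome biogenesis rose in 25 of 27 (25 over the list alone, median 1.75), with LYAR at 3.36 ± 0.29. Cholesterol synthesis fell in 21 of 23 (22 over the list alone, median -1.57), with INSIG1 at -3.19 ± 0.24 and FDFT1 at -2.58 ± 0.13. Quiescence and FOXO targets fell in 14 of 17 (14 over the list alone, median -2.37), with CDKN1C, a brake on cyclin-dependent kinases, at -3.95 ± 0.40. Autophagy and lysosome genes fell in 13 of 17 (15 over the list alone, median -0.60), with GABARAPL1 at -2.98 ± 0.44 and SQSTM1 at -1.62 ± 0.17. Camera with an estimated correlation gave adjusted p = 0.694 for ribosomal proteins (0 up and 12 down; 0 and 7 over the list alone), 0.367 for other 5TOP genes (7 down of 19; 7 over the list alone) and 0.214 for mitochondrially encoded mRNAs (7 down of 12; 7 over the list alone). It also ended the list calls of fatty acid synthesis (0.0604), extracellular matrix genes (0.548) and the respiratory chain (0.673), all Benjamini-Hochberg adjusted.

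The contrast of 10 h with 5 h asked how the early response gave way to the cell cycle. The cytokine CXCL8 fell 26.8-fold from 1248 ± 84.5 to 46.8 ± 7.17 CPM (-4.74 ± 0.20), PTGS2, which makes prostaglandins, fell 27-fold (-4.75 ± 0.29) and IL6 fell 22.9-fold (-4.52 ± 0.40). CCNA2, cyclin A2 of S phase, rose 22.2-fold from 4.94 ± 1.83 to 115 ± 31.1 CPM (4.47 ± 0.29), and the origin-binding ORC1 rose 30.1-fold (4.91 ± 0.31). TXNIP rose back by 6.7-fold to 122 ± 5.09 CPM (2.74 ± 0.19). Of 1726 called genes, 887 were higher and 839 lower (1178 and 1275 with the replicate number as a block), with large rises also in SHCBP1 (4.59 ± 0.24), EXO1 (4.55 ± 0.29) and MYBL2 (4.50 ± 0.43) and large falls in SHC4 (-5.06 ± 0.47), ANGPTL4 (-3.08 ± 0.33) and TRIB3 (-3.04 ± 0.33). All 31 G1/S E2F targets rose (31 over the list alone, median 3.08), as did 22 of 24 G2/M genes (24 over the list alone, median 2.67) and 18 of 19 histones (19 over the list alone, median 2.5). NF-kB and cytokine genes fell in 12 of 13 (13 over the list alone, median -1.96) and immediate-early genes in 8 of 14 (8 over the list alone, median -0.99), as in SPRY2 (-1.89 ± 0.16). ER chaperones fell in 9 of 19 (9 down and 1 up over the list alone), as in DNAJB9 (-2.60 ± 0.25) and HERPUD1 (-2.58 ± 0.20). With an estimated correlation the adjusted p of immediate-early genes was 0.13 and that of ATF4 and amino acid response genes (1 up and 9 down of 20; 2 and 10 over the list alone) was 0.335, which ended those list calls.

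**Figure D2:**
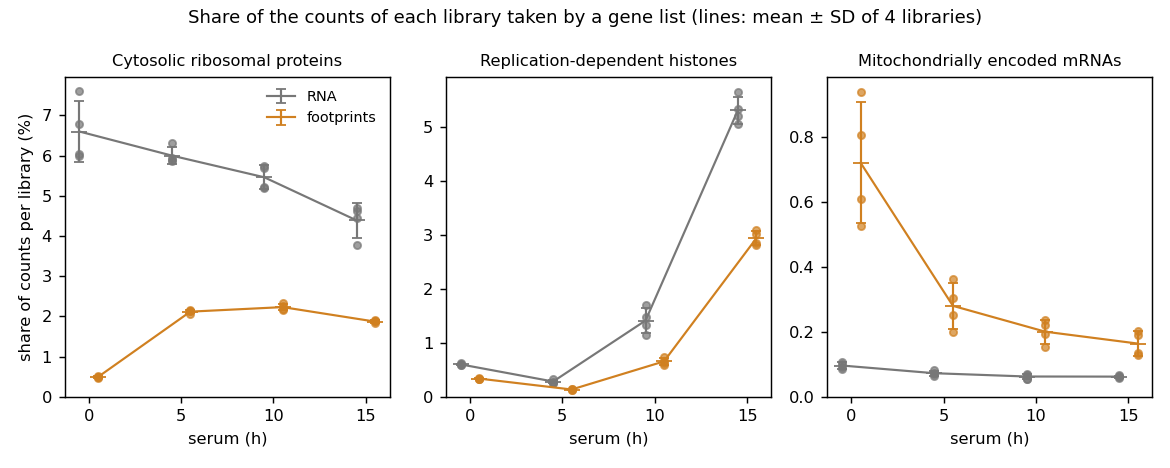
Share of all counts from ribosomal protein, replication-dependent histone and mitochondrially encoded genes in every library of both assays. Footprints of ribosomal proteins went from 0.492 ± 0.0212% at 0 h to 2.12 ± 0.0356% at 5 h (mean ± SD, n = 4).

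The next question was what marked 15 h. Histone mRNAs, made when DNA is copied, were among the largest rises. H1-5 rose 54.9-fold from 50.4 ± 7.13 to 2757 ± 277 CPM (5.78 ± 0.19) and H2BC11 rose 42.7-fold from 134 ± 20.8 to 5712 ± 844 CPM (5.41 ± 0.17). Histones made up 0.60 ± 0.0166% of RNA counts at 0 h, 0.283 ± 0.0315% at 5 h, 1.41 ± 0.230% at 10 h and 5.31 ± 0.251% at 15 h. All 19 rose against 0 h (19 over the list alone, median 3.65). G2/M genes rose in 21 of 24 (21 over the list alone, median 2.16), with the mitotic kinase CDK1 at 4.78 ± 0.38, AURKB at 3.64 ± 0.24 and TOP2A at 3.63 ± 0.21, and CCNA2 stood 11.9-fold above 0 h. G1/S E2F targets rose in 31 of 31 (31 over the list alone, median 2.81). Of 8775 genes, 4463 were called, 2232 higher and 2231 lower. Other large rises were FAM111B (6.12 ± 0.50), H2AC14 (5.95 ± 0.23), H2AC16 (5.67 ± 0.23), ESCO2 (5.56 ± 0.52) and ERCC6L (5.51 ± 0.40).

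Sterol and quiescence genes were far below 0 h. HMGCS1, which commits acetyl-CoA to sterol synthesis, fell 8.98-fold from 555 ± 59.5 to 62.1 ± 14.2 CPM (-3.17 ± 0.19), and 21 of 23 cholesterol genes fell (21 over the list alone, median -1.96). Fatty acid synthesis fell in 7 of 11 and rose in 1 (7 and 1 over the list alone, median -1.03), with SCD at -3.28 ± 0.18. Quiescence and FOXO targets fell in 15 of 17 (15 over the list alone, median -2.03), as in YPEL3 (-4.46 ± 0.37). DDIT4 (-6.19 ± 0.37), TCP11L2 (-6.16 ± 0.38), PPL (-5.28 ± 0.41) and BMF (-4.75 ± 0.67) fell most. Ribosomal protein mRNAs fell slightly, 34 of 62 (36 over the list alone, median -0.43), with RPS9 at -0.91 ± 0.14, and other 5TOP genes fell in 8 of 19 (8 over the list alone), with EEF2, the translation elongation factor 2, at -1.76 ± 0.21. The respiratory chain had 2 up and 20 down of 45 (2 and 20 over the list alone, median -0.42), with NDUFB11 at -1.03 ± 0.13. With an estimated correlation the adjusted p was 0.419 for ribosomal proteins, 0.267 for other 5TOP genes, 0.503 for the respiratory chain, 0.0772 for fatty acid synthesis, 0.0798 for SRF and YAP targets (11 up and 2 down of 17; 11 and 2 over the list alone) and 0.165 for ER chaperones (12 up and 2 down of 19; 12 and 2 over the list alone), which ended these list calls.

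The step from 10 h to 15 h, which asked how cells moved towards mitosis, had the fewest called genes in RNA. The chromatin linker histone H1-3 rose 8.31-fold from 29.2 ± 8.42 to 246 ± 31.2 CPM (3.05 ± 0.25), and KIF20A rose 5.8-fold (2.54 ± 0.17). All 24 G2/M genes rose (24 over the list alone, median 1.80), with CENPF at 2.67 ± 0.25, and all 19 histones rose (19 over the list alone, median 2.08). ER chaperones fell in 5 of 19 (12 over the list alone, median -0.44), as in SDF2L1 (-1.14 ± 0.24). The fixed gene CCNB1, cyclin B1 of mitosis, rose 3.12-fold (1.64 ± 0.18), the p53 target CDKN1A rose 1.83-fold (0.88 ± 0.20), and GBP2 (-2.10 ± 0.24), GFPT2 (-1.75 ± 0.18) and BMP2 (-1.55 ± 0.24) fell. There were 519 called genes, 334 higher and 185 lower. Leaving out 1 library gave as few as 333, and the replicate number as a block gave 1170, 629 higher and 541 lower, so the balance of directions depended on the block. Another split, which parts the libraries numbered 1 from those numbered 2, gave 745 calls against 378 for the real split (287 higher and 91 lower), so splits that ignore the number did not exclude chance for this count.

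Footprints were then compared at 5 h, to ask which genes gained them, through more mRNA, more ribosomes per mRNA or both. The ribosomal protein mRNAs, whose 5TOP start sequence ties their translation to mTORC1, gained footprints. RPL32 rose 7.05-fold from 72.7 ± 3.66 to 514 ± 18.8 CPM (2.82 ± 0.06), and EEF1A1, a translation elongation factor, rose 11-fold from 11.4 ± 2.27 to 124 ± 19.8 CPM (3.46 ± 0.13). All 62 ribosomal proteins tested, of 79 listed, rose (62 over the list alone, median 2.5), with RPS18 at 3.54 ± 0.12 and RPL37A at 3.39 ± 0.08. All 19 other 5TOP genes rose (19 over the list alone, median 2.01), as did all 29 ribosome biogenesis genes (29 over the list alone, median 1.64). SERPINB2 rose from 1.04 ± 0.167 to 1279 ± 55.2 CPM (10.24 ± 0.14), CXCL8 from 0.177 ± 0.135 to 403 ± 78 CPM (10.86 ± 0.36, from 4 counts over the 0 h libraries), and PTGS2 (8.79 ± 0.36), BMP2 (6.19 ± 0.18), F3 (5.79 ± 0.08) and ADAMTS1 (5.75 ± 0.09) also rose. SLC2A12 (-5.96 ± 0.16), IFIT2 (-5.22 ± 0.15), KIF20A (-5.16 ± 0.20), IFIT1 (-4.95 ± 0.11) and TXNIP (-4.94 ± 0.08) fell most. Of 10959 genes, 8297 were called, 3858 higher and 4439 lower (3993 and 3973 when only the groups compared were fitted). Of the 8297, 2773 changed more than 2-fold in their estimate.

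ER chaperones rose in all 19 (19 over the list alone, median 1.83), and SRF and YAP targets in 17 of 18 (17 over the list alone, median 1.49), with TAGLN at 3.94 ± 0.08. Quiescence and FOXO targets fell in 19 of 20 (19 over the list alone, median -1.51) and cholesterol genes in 22 of 23 (22 over the list alone, median -0.99). These, with the ribosomal, other 5TOP and biogenesis lists, held with an estimated correlation. G2/M genes fell in all 24 (24 over the list alone, median -2.63; adjusted p = 0.0765 with an estimated correlation, Benjamini-Hochberg), and histones in 18 of 19 (18 over the list alone, median -1.04; adjusted p = 0.211). NF-kB and cytokine genes rose in 14 of 16 (14 over the list alone, median 2.88; adjusted p = 0.0632) and immediate-early genes in 16 of 20 with 3 down (16 and 3 over the list alone, median 1.94; adjusted p = 0.0518), as in FOSL1 (4.46 ± 0.08). All 20 aminoacyl-tRNA synthetases rose (20 over the list alone, median 0.93; adjusted p = 0.0632), and all 13 mitochondrially encoded mRNAs fell (13 over the list alone, median -1.03), though camera did not call the list (adjusted p = 0.108). VIM, the mesenchymal filament vimentin, rose (2.03 ± 0.06) among 6 up and 4 down of 10 epithelial and mesenchymal markers (6 and 4 over the list alone; adjusted p = 0.157 with an estimated correlation).

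At 10 h footprints asked whether replication genes were also being translated. CCNE2 rose 118-fold from 1.04 ± 0.582 to 131 ± 6.85 CPM (6.89 ± 0.16), FAM111B rose 106-fold (6.72 ± 0.14) and the replication factor MCM10 rose 102-fold (6.67 ± 0.16), followed by DTL (6.32 ± 0.17) and CDC6 (6.10 ± 0.10). The cell-cycle inhibitor CDKN1C fell 49.3-fold from 49.7 ± 4.63 to 1.01 ± 0.428 CPM (-5.62 ± 0.16), with SLC2A12 (-6.01 ± 0.15), TCP11L2 (-5.87 ± 0.16) and KLHL24 (-4.89 ± 0.15) also low. All 33 G1/S E2F targets rose (33 over the list alone, median 3.61), all 62 ribosomal proteins rose (62 over the list alone, median 2.59) and all 23 cholesterol genes fell (23 over the list alone, median -1.70). There were 8597 called genes, 4322 higher and 4275 lower. Histones rose in 18 of 19 (18 over the list alone, median 1.5; adjusted p = 0.126 with an estimated correlation, Benjamini-Hochberg), G2/M genes had 17 up and 5 down (17 and 5 over the list alone; adjusted p = 0.483), and mitochondrially encoded mRNAs fell in 13 of 13 (13 over the list alone, median -1.65; adjusted p = 0.629). Against 5 h, 6762 genes were called, 3396 higher and 3366 lower. All 24 G2/M genes rose (24 over the list alone, median 3.69), and NF-kB and cytokine genes fell in 16 of 16 (16 over the list alone, median -2.31), led by IL6, down 67.5-fold (-6.08 ± 0.15), and PTGS2 (-4.85 ± 0.21). NCAPH (5.29 ± 0.13), EXO1 (5.24 ± 0.12) and CDC45 (5.11 ± 0.14) were among the largest rises, and HMOX1 fell (-3.34 ± 0.08). Ribosomal proteins had 13 up and 3 down of 62 (6 and 3 over the list alone; adjusted p = 0.952 by camera, Benjamini-Hochberg).

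At 15 h the footprints of histones and mitotic genes were compared with 0 h. The replication gene RRM2 rose 52.8-fold from 6.22 ± 1.58 to 318 ± 25 CPM (5.72 ± 0.10), the proliferation marker MKI67 rose 16.5-fold from 99.4 ± 18.3 to 1633 ± 119 CPM (4.05 ± 0.14), and H2BC14 rose 82.6-fold (6.37 ± 0.16). FBXO5 (6.41 ± 0.11), H2AC16 (6.23 ± 0.11), CDC45 (6.19 ± 0.15) and CLSPN (5.89 ± 0.10) rose, and TCP11L2 (-6.40 ± 0.17), DDIT4 (-5.29 ± 0.17) and INSIG1 (-4.10 ± 0.08) fell. Histones took 0.337 ± 0.0125% of footprints at 0 h and 2.94 ± 0.130% at 15 h. Of 8736 called genes, 4399 were higher and 4337 lower. All 33 G1/S E2F targets (33 over the list alone, median 3.75), 19 histones (19, median 3.90) and 62 ribosomal proteins (62, median 2.36) rose. All 24 G2/M genes rose (24 over the list alone, median 2.78; adjusted p = 0.0555 with an estimated correlation, Benjamini-Hochberg). Proteasome subunits rose in 26 of 29 and fell in 1 (26 and 1 over the list alone, median 0.63; adjusted p = 0.233), as in PSMD14 (1.58 ± 0.05), and autophagy genes fell in 17 of 20 and rose in 1 (17 and 2 over the list alone, median -0.88; adjusted p = 0.0658). Mitochondrially encoded mRNAs fell in 13 of 13 (13 over the list alone, median -1.92; adjusted p = 0.654), as in MT-ATP8 (-2.64 ± 0.38) and MT-CO2 (-2.11 ± 0.24). Against 10 h, 4493 genes were called, 2275 higher and 2218 lower, of which 387 had an estimate over 2-fold. H3C4 (3.83 ± 0.18), H1-3 (3.26 ± 0.09) and KIF20A (2.88 ± 0.14) rose, CDKN1A rose 2.11-fold (1.08 ± 0.06), and BMP2 (-2.41 ± 0.14) fell. Over that step 42 of 62 ribosomal proteins fell by small amounts (44 over the list alone, median -0.20; adjusted p = 0.383 with an estimated correlation), and CD68, the blood cell marker, fell (-0.18 ± 0.07).

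**Figure D3:**
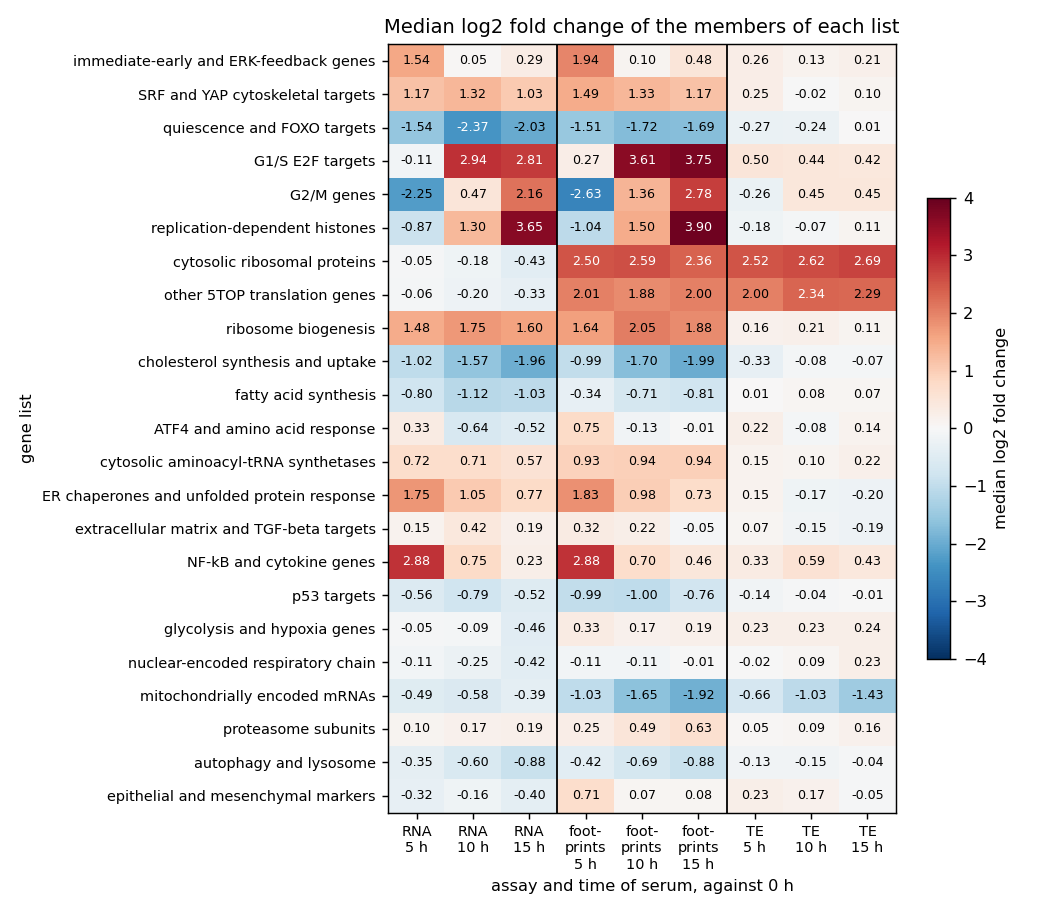
Median log2 change of each gene list against 0 h in RNA, footprints and translational efficiency. The ribosomal protein list had medians of -0.05 in RNA and 2.5 in footprints at 5 h.

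The assays were set side by side to ask how far footprints followed mRNA. F3 had 5.59 ± 0.19 in RNA and 5.79 ± 0.08 in footprints at 5 h, and TXNIP had -5.11 ± 0.19 and -4.94 ± 0.08. HMGCS1 had -3.17 ± 0.19 and -3.25 ± 0.07 at 15 h, and PCNA had 3.22 ± 0.20 and 3.20 ± 0.07. RPL32 had -0.06 ± 0.19 in RNA, not called, and 2.82 ± 0.06 in footprints at 5 h. Over 8736 genes the log2 changes of the assays, which share no libraries, correlated with r = 0.854 at 5 h, 0.883 at 10 h and 0.886 at 15 h. These are correlations across genes, which are not independent replicates. Of the genes called in both assays, 2948 of 3002 at 5 h, 3669 of 3751 at 10 h and 3993 of 4135 at 15 h changed in the same direction. Genes opposed between the assays numbered 54, 82 and 142.

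**Figure D4:**
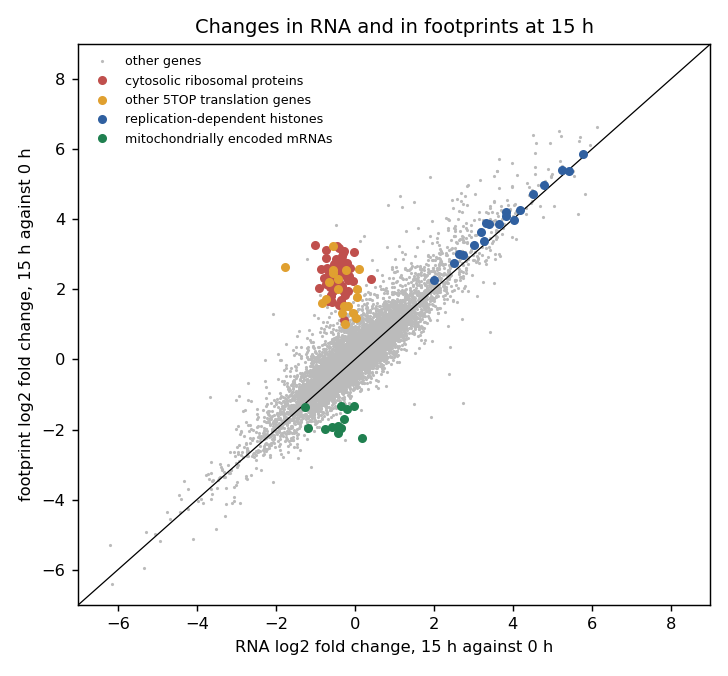
Log2 change at 15 h against 0 h in RNA and in footprints for 8736 genes, r = 0.886.

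The last question was which genes changed in translational efficiency (TE), footprints per mRNA. At 5 h the 5TOP mRNAs stood apart. EEF2 rose 21.2-fold in TE (4.41 ± 0.24), with RNA at 9714 ± 892 and 3788 ± 1026 CPM and footprints at 612 ± 68.7 and 5215 ± 262 CPM at 0 h and 5 h. All 62 ribosomal proteins rose (62 over the list alone, median 2.52; adjusted p = 6.19e-11 with an estimated correlation, Benjamini-Hochberg), as in RPL13A (3.59 ± 0.18), RPS18 (3.55 ± 0.23) and RPS2 (3.52 ± 0.16). All 19 other 5TOP genes rose (19 over the list alone, median 2.0; adjusted p = 3.27e-11), as in EEF1G (3.46 ± 0.14) and EEF1A1 (3.25 ± 0.24). The ADP/ATP carrier SLC25A6 (3.84 ± 0.20), the replication licensing factor CDT1 (3.83 ± 0.48), VIM (2.36 ± 0.15) and GAPDH (1.46 ± 0.12) also rose. SAT1, a polyamine-degrading enzyme, fell 3.62-fold in TE (-1.86 ± 0.14), with RNA at 141 and 308 CPM and footprints at 32.2 and 20 CPM, and CIT (-2.71 ± 0.34), KIF14 (-2.45 ± 0.44), ZNF608 (-2.45 ± 0.38) and MMP15 (-1.85 ± 0.40) fell. MYC (-0.01 ± 0.21), CCND1 (0.07 ± 0.21) and TXNIP (0.14 ± 0.22) were not called. In all, 565 of 8736 genes were called, 361 higher and 204 lower (585 and 463 with the replicate number as a block). G1/S E2F targets had 5 up of 31 (8 up and 1 down over the list alone, median 0.50; adjusted p = 0.45 with an estimated correlation), and ribosome biogenesis 4 up of 27 (5 over the list alone, median 0.16; adjusted p = 0.27).

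TE at 10 h asked whether the 5TOP change lasted. EEF2 stood at 4.33 ± 0.24, SLC25A6 at 3.92 ± 0.20, RPS18 at 3.91 ± 0.23 and EEF1G at 3.77 ± 0.14. Ribosomal proteins rose in 61 of 62 (62 over the list alone, median 2.62; adjusted p = 5.91e-11 with an estimated correlation, Benjamini-Hochberg) and other 5TOP genes in 19 of 19 (19 over the list alone, median 2.34; adjusted p = 2.66e-11). The kinetochore gene SKA3 rose (3.27 ± 0.35), as did CDT1 (2.97 ± 0.37), RRM2 (2.13 ± 0.41) and UBE2C (1.68 ± 0.25), and MMP15 (-1.98 ± 0.43) and SAT1 (-1.49 ± 0.16) fell. There were 632 called genes, 475 higher and 157 lower (670 and 348 with the replicate number as a block). G1/S E2F targets rose in 9 of 31 (13 over the list alone, median 0.44) and G2/M genes in 9 of 24 (9 over the list alone, median 0.45), each at adjusted p = 0.437 with an estimated correlation.

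At 15 h ribosomal proteins rose in 62 of 62 in TE (62 over the list alone, median 2.69; adjusted p = 2.26e-10 with an estimated correlation, Benjamini-Hochberg) and other 5TOP genes in 19 of 19 (19 over the list alone, median 2.29; adjusted p = 2.11e-10). EEF2 was at 4.26 ± 0.24, CDT1 at 3.41 ± 0.38, SKA3 at 3.37 ± 0.34 and GAPDH at 1.72 ± 0.12. Histones had 0 of 19 called (0 over the list alone, median 0.11), so their footprints kept pace with their mRNA within error. G2/M genes rose in 9 of 24 (13 over the list alone, median 0.45) and G1/S E2F targets in 9 of 31 (13 over the list alone, median 0.42), each at adjusted p = 0.426 with an estimated correlation. Proteasome subunits rose in 6 of 29 (7 over the list alone; adjusted p = 0.393), as in PSMB5 (0.98 ± 0.16), and the respiratory chain had 5 up of 45 (5 over the list alone; adjusted p = 0.605), as in COX5A (0.97 ± 0.17). Mitochondrially encoded mRNAs fell in 8 of 12 (11 over the list alone, median -1.43; adjusted p = 0.249), with MT-CO2 at -1.81 ± 0.33, MT-ND4 at -1.71 ± 0.31, MT-ND5 at -1.60 ± 0.35 and MT-CO1 at -1.46 ± 0.31, and none of these genes was called by limma voom with 1 variance weight per assay. There were 958 called genes, 614 higher (64.1%) and 344 lower (874 and 668 with the replicate number as a block). Scaling all 32 libraries together gave 1124, of which 520 were higher (46.3%), so the balance of directions at 15 h depended on scaling.

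**Figure D5:**
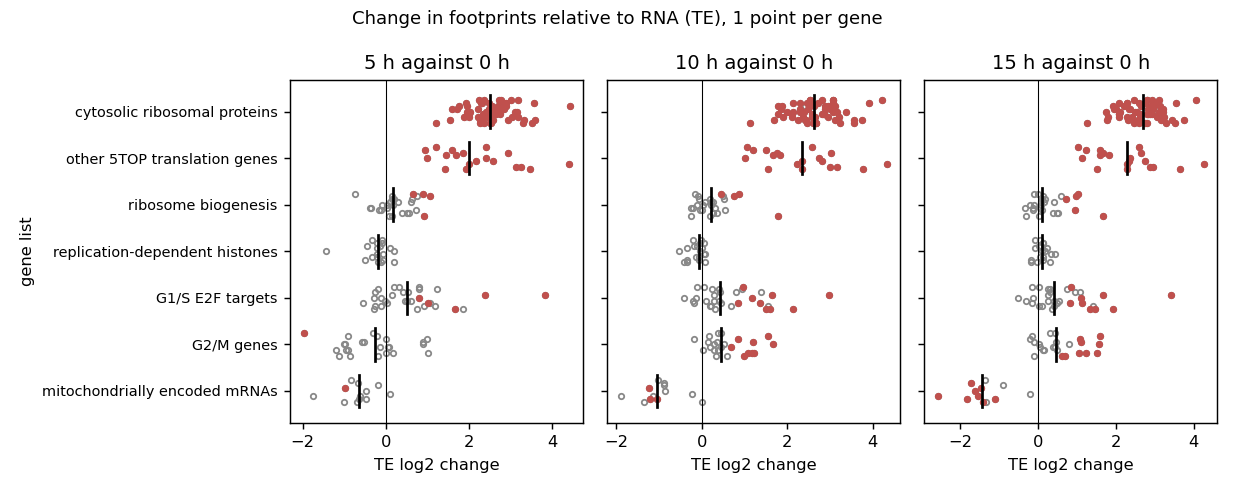
Change of translational efficiency at 5 h, 10 h and 15 h against 0 h for members of 5TOP, cell-cycle, histone and mitochondrial lists. All 62 ribosomal proteins tested were called higher at 5 h.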

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

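Of the tests in this part, the sorting of TE splits by whether an assay keeps its times whole, the exact tests of variation between libraries, of a common factor and of footprints with the RNA fall taken off, the gene-by-gene count of mitochondrial messages and the tests of the RNA axis against depth and against the replicate number were chosen after the result was seen, and limma voom was added after seeing the data.

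Of 216 groups of 4 libraries tested, each for 1 library or gene measure, 4 had a library far from the others, and chance alone gives about 1 in 20 groups, or 10.8. Among them were the TMM factor of footprint replicate 3 at 15 h (0.929), the CPM of CCNB1 in footprint replicate 2 at 15 h (660.8) and of RPL32 in footprint replicate 1 at 15 h (451.3). RNA and footprint changes differed by the interaction test in 565 genes at 5 h, 632 at 10 h and 958 at 15 h. Under 100 splits of the libraries of both assays each of these counts was reached by 4 splits, the real one included, with 567, 508 and 880 called genes for the real split and up to 2981, 5930 and 5135 for another. Each of those other splits keeps the times of at least 1 assay whole, while the times of the other assay are mixed or, in the split with 5930, set the opposite way (RNA of 0 h with footprints of 10 h), so effects of serum enter their counts. The share of 0.04 lay under 0.05 by less than its sampling error of 0.02, so over all drawn splits chance was not firmly excluded. The other splits that keep neither assay whole, 94 at 5 h, 95 at 10 h and 96 at 15 h, called at most 0, 0 and 1 genes. Such splits mix the times in both assays, which puts the change with time into the spread, so their low counts decide little.

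Footprints of mitochondrially encoded mRNAs fell as a share of all footprints, by 2.13 on the log2 scale at 15 h against a fall by 0.627 in RNA. The exact 2-sided p of the footprint fall was 0.0286, the smallest that 4 against 4 libraries can give, which argues against variation between libraries. Fewer mitochondrial mRNAs as the whole cause was argued against by the shares, whose falls differed by -1.50 ± 0.27: with the largest fall between any RNA libraries (0.908) added back, footprints were still lower by 1.22 (exact permutation p = 0.0286). The planned permutation test of the difference (p = 0.0698, 4900 arrangements) shuffled times within each assay, so its null was no fall in either assay rather than equal falls, and it decided nothing. Gene by gene, 8 of 12 messages were called lower in TE at 15 h; limma voom with 1 variance weight per assay ended these calls with similar folds (MT-CO2 -1.81 ± 0.33 before and -1.80 ± 0.68 after, MT-ND4 -1.71 ± 0.31 and -1.70 ± 0.60), because its standard errors were 1.23 to 2.35 times as large over the 12. A single common factor as the whole cause, such as the yield of mitochondrial ribosome fragments or a rise of all cytosolic footprints, was argued against by falls that differed between the 13 messages from -2.64 to -1.32 (Cochran Q 25.2, p = 0.0139; exact permutation p = 0.0286 with each library centred on its mean over the messages, again the smallest possible). An equal fall of translation over all mitochondrial messages would also be a single common factor, so as the whole cause these differences count against it equally. Both tests used footprint changes and not TE, so they do not address an equal fall per mRNA beside mRNA changes that differ between messages. Lower mitochondrial translation relative to cytosolic translation, alone or with changes of mRNA, may explain the fall. Whether the change per mRNA differs between messages was not tested. A common factor of any of these kinds as part of the fall and a message-dependent loss of fragments stay open.

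Some cell-cycle genes had a higher TE, 9 of 31 G1/S E2F targets at 10 h and 9 of 24 G2/M genes at 15 h. A technical cause would be RNA changes compressed at a low RNA level, which random lists matched on RNA change and level should then share. The median TE change of G1/S E2F targets at 10 h (0.44) lay at percentile 100 of 10000 such lists (median -0.05, 95% of them from -0.18 to 0.19, highest 0.43), and that of G2/M genes at 15 h (0.45) at percentile 99.98 (median -0.01, 95% of them from -0.22 to 0.23, highest 0.51). The matched genes had RNA changes lower by 0.27 and 0.10 on average, so the match was not complete. They were also picked by the RNA change that is subtracted in TE. Error in that estimate can lower the TE of the matched genes, so the comparison does not settle compression. Better translation of these messages may contribute, as a hypothesis, though camera with an estimated correlation called neither list.

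RNA libraries of a time differed along 1 axis holding 36.2% of the variance within times (10.0% on the next), with extracellular matrix (1.24 SD) and immediate-early genes (1.06 SD) at its high end. No link with depth was seen over 16 libraries (r = 0.193, permutation p = 0.526, rho = 0.262, r = 0.21 without the 2 farthest). So few libraries cannot exclude a moderate link, so depth as a source stays open. A culture effect shared by footprints of the same time and number was not seen either (r = -0.262, permutation p = 0.401, rho = -0.127, r = -0.117 without the 2 farthest), but the labels do not say that same-numbered libraries share a culture. The replicate number held 76.4% of its variance (permutation p = 0.0125, adjusted over 3 tests 0.0375). A batch of RNA handling that follows the number may explain it, and a biological difference between cultures was not tested in another way.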

How the results depend on the processing

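RNA had fewer counts per library than footprints, with 8775 genes tested at a common biological coefficient of variation of 0.185 against 10959 at 0.0547, so counts of called genes are not comparable between assays. How far depth alone limits the RNA calls was not tested. Leaving out the RNA libraries numbered 2, leaving out the footprint libraries numbered 1 at 0 h and 15 h, and limma voom were chosen after seeing the data. Without the RNA libraries numbered 2, the counts at 5 h, 10 h and 15 h against 0 h, 10 h against 5 h and 15 h against 10 h were 3001, 3653, 4163, 1434 and 425 in RNA, and 769, 756 and 1246 in TE at 5 h, 10 h and 15 h. Which direction held more called genes turned under at least 1 alternative in RNA at 5 h and 15 h against 0 h and 10 h against 5 h, in all 5 footprint contrasts and in TE at 15 h. Under the alternatives, 0 directions were reversed among called named genes and among lists called both as reported and under the alternative, while medians of some lists that were not called changed sign.

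Counting only called genes with an estimate over 2-fold, the numbers at 5 h, 10 h and 15 h against 0 h, 10 h against 5 h and 15 h against 10 h were 1542, 1972, 2382, 880 and 255 in RNA and 2773, 3389, 3636, 1444 and 387 in footprints, and 264, 314 and 373 in TE at 5 h, 10 h and 15 h, fewer by construction. With the replicate number as a block, which the labels do not say pairs the samples, RNA at 15 h against 10 h gave 1170 (629 higher and 541 lower, against 334 and 185) and TE 1048, 1018 and 1542. The data gave a hint of such structure in RNA, where 14 of 20 pairs of same-numbered libraries correlated above 0.1 against 1 of 20 in footprints. In RNA 10 of 20 and in footprints 12 of 20 correlated best with their own number, where chance gives about 1 in 4, so not every library did. The mitochondrially encoded share of footprints was higher in libraries numbered 1 and 2 than in those numbered 3 and 4 at each time. At 0 h it was 0.942% and 0.807% against 0.528% and 0.611%. DESeq2 gave 899, 950 and 1442 in TE, and it had more false calls in the simulated data. For gene lists called, an estimated correlation gave 8 of 13, 10 of 16, 7 of 13 and 3 of 5 in RNA at 5 h, 10 h and 15 h against 0 h and 15 h against 10 h, 7 of 20, 9 of 17, 9 of 15 and 3 of 10 in footprints, and 2 of 8, 2 of 5 and 2 of 9 in TE. Fry, which does not compare with other genes, gave 20, 14 and 9 in RNA at 15 h against 0 h, 10 h against 5 h and 15 h against 10 h, 23, 17 and 16 in footprints, and 11 in TE at 10 h. Where no construction is named, the cause was not tested.

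Leaving out 1 library gave 2602 to 3172, 3410 to 3879, 4001 to 4373, 1358 to 1641 and 333 to 717 in RNA, 8028 to 8239, 8369 to 8597, 8572 to 8780, 6391 to 6634 and 3918 to 4380 in footprints, and 439 to 733, 548 to 698 and 790 to 1165 in TE. RNA at 15 h against 10 h fell from 519 by more than 1.5 times without RNA 10 h replicate 3 (333), RNA 15 h replicate 1 (341) or RNA 15 h replicate 4 (343). Limma voom gave 424, 474 and 725 in TE, and in the simulated data it had fewer false calls than edgeR QL and recovered fewer changed genes. TMM over all 32 libraries gave 552, 631 and 1124 in TE, of which 864 at 15 h were shared with the 958, and moved the median of all genes at 15 h from -0.04 to -0.12. Without a filter the median of all genes was -0.10 in RNA at 10 h and 15 h. Over 490 values of named genes, RLE factors ended 2 calls and added 1, and over 4832 values with 1 library left out, 107 calls ended and 22 were added. RLE factors changed the sign of 5 of 325 list medians, 0 of them of called lists, by at most 0.0458.

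Over 35 splits of the same libraries, only the real split gave a result as large, with 0 called genes as the highest other. This held in RNA at 5 h, 10 h and 15 h against 0 h and 10 h against 5 h (3070, 3440, 4179 and 1461 for the real split). It also held in all 5 footprint contrasts (7966, 8379, 8434, 6613 and 4605). A share of 1 in 35 is the smallest these splits can give, which argues against chance there. Splits that mix the times put the change with time into the spread, so their 0 calls are no estimate of false calls. For RNA at 15 h against 10 h, 2 of 35 splits gave a result as large, with 378 for the real split. The other, with 745, swaps 10 h replicate 1 with 15 h replicate 2. That split parts the libraries numbered 1 from those numbered 2 and points to a structure among the libraries. Chance was not excluded by these splits, which ignore the number, while the block on the number gave 1170.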

Other observations

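The lists in this part were written after the first results were seen, and interferon genes already seen among the most changed were left out of the interferon list. The tests on them were chosen before their results were seen, with p adjusted by Benjamini-Hochberg over 36 tests.

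Interferon-stimulated genes may fall after serum. Of 23 tested in RNA, 0 rose and 10 fell at 5 h (median -0.60), as in IRF1 (-2.50 ± 0.29) and IFIT3 (-2.29 ± 0.32), and in footprints 0 rose and 24 fell of 29 (median -0.76). Camera gave an adjusted p of 0.00205 at the preset correlation and 0.0988 with an estimated correlation for RNA at 5 h, so the list as a whole was not called at that stricter setting. At 10 h 0 rose and 17 fell in RNA (median -1.18), and at 15 h 1 rose and 14 fell (median -1.16).

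Serum makes many cells resorb the primary cilium, so cilium and Hedgehog genes were tested in footprints at 15 h. Of 48 cilium genes, 13 rose and 30 fell (median -0.44; adjusted p = 0.344 with an estimated correlation), and of 9 Hedgehog genes 1 rose and 5 fell (median -1.29; adjusted p = 0.529), as in PTCH1 (-1.29), BOC (-1.80) and HHIP (2.25). A loss of the programme as a whole was not shown.

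Serum is known to reset circadian clocks, and clock genes may be among its early targets here, though elapsed time without serum was not sampled. In RNA at 5 h 7 of 11 were called, 4 higher and 3 lower, with DBP at -3.01, NR1D2 at -2.33 and BMAL1 at 1.73. That number lay at percentile 97.1 of 10000 random lists matched on mean CPM, whose median was 4, and the clock genes had no shared direction (median 0.27).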
